A study of Mus musculus with 2 samples.

How the data were processed

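H3K9ac, the acetylation of lysine 9 on histone H3, was measured by ChIP-seq in forebrain of B6NCrl mouse embryos at day 13.5, with male and female embryos pooled. The samples form 1 group of 2 biological replicates. Chromatin fragments were selected at 300 to 500 bp per the labels. No samples of another tissue, stage or condition belong to the series.

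The 4 files analysed are peak lists in narrowPeak format on mouse build mm10. Per the file headers, each replicate's list was called from that replicate's alignment with a control, the pooled list from both alignments with both controls, and the replicated list was derived from the pooled list and both replicate lists. The deposited signal value of a peak was read as a measure of its enrichment within its own list, as the narrowPeak format intends. The deposited significance of a peak is given as −log10 p and −log10 q within its own list. The caller, its version and threshold, any filter on problem regions, the exact definition of the signal value and the rule for keeping a replicated peak are not given in the sources used here. Signal values were therefore ranked or compared only within a list, or by rank between lists. The lowest −log10 p was 2.01 in replicate 1, 2.01 in replicate 2, 2.01 in the pooled list and 2.04 in the replicated list.

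The number of sequenced reads per replicate is not given in the sources used here, so the depth is unknown and no interval was computed for a signal value. Shares of peaks and of genes carry exact Clopper-Pearson binomial intervals at 95% confidence. These cover counting error only: neighbouring genes and peaks are not independent, and they are not replicates. Errors between replicates are standard deviations over the 2 replicate lists. Those lists were each called alone and rest on fewer reads than the pooled list, so the 2-replicate mean can lie away from the replicated list's value. The signal values given for single genes come from the replicated list, which holds a single value per peak and so has no replicate error.

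Peaks were placed on GRCm38.p6, in which 21 of 21 chromosomes had the same length as in mm10, and on GENCODE mouse release M21. Chromosomes 1 to 19, X and Y were analysed, and peaks on other contigs were left out because random placements and gene territories need assembled chromosomes. They numbered 11 in replicate 1, 12 in replicate 2, 14 in the pooled list and 9 in the replicated list. Coordinates are 1-based on mm10. A protein-coding gene was called marked when a replicated peak lay within 1 kb of the start site of any of its protein-coding transcripts. Domain width of a marked gene was the number of bp under replicated peaks within 5 kb of its start sites. The windows of all its start sites were joined, so the possible width grows with their number and spread. A distal peak lay over 2.5 kb from every protein-coding start site and was given to the gene with the nearest start site. Merged domains joined replicated peaks over gaps of at most 1 kb. CpG content was the observed over expected CpG ratio within 500 bp of each gene's most upstream protein-coding start site, in deciles of 21853 genes. A gene marked only at another of its start sites was thus matched by a promoter other than the marked one. Shared promoter sequence was the share of 50-mers in the same window that also occurred in that of another gene.

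Overlap between replicate lists was set against 100 random placements of the other list on the same chromosome (bedtools shuffle), and peak locations against 100 random placements of the replicated list. Marked promoters in 18 gene lists were compared with all other protein-coding genes by Fisher's exact test, two-sided. Domain widths of the lists were compared with 10000 random lists of marked genes. Distal peaks per gene were compared with 10000 random lists matched on decile of territory, the bp nearest to each gene's start sites. Each comparison with random lists is a permutation test over genes, so an exact p refers to Fisher's test and a permutation p to random lists. The same holds for lists matched on CpG decile. The smallest two-sided p that the random lists can give is 0.0002. P values were adjusted by the Benjamini-Hochberg method over the 18 lists within each test, with a threshold of 0.05. Chromosome X was compared with the autosomes by Fisher's exact test, two-sided. No p value was given for differences between peaks, since there is no second group of samples.

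The lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The lists held telencephalic patterning and neurogenic transcription factors, radial glia and neural progenitors, newborn neurons and cortical layer fate, diencephalon and hypothalamus regulators, midbrain and hindbrain regulators, Hox genes, glia and mature neuron genes, erythroid cells, endothelium and pericytes, microglia and macrophages, meninges and mesenchyme, choroid plexus and ependyma, liver, heart and skeletal muscle, limb and genital regulators, gut, lung and pancreas epithelium, germ cell and meiosis genes, and ribosomal proteins. They were drawn from textbook knowledge and not from these samples. A gene on a list of another cell type or organ can also be active in forebrain. Pax6, Otx2, Lmx1b, Ptf1a, Pdgfra, Sox17, Msx1, Ttr and Foxa3 each stood on 2 lists. The rule named up to 4 marked genes of each list by highest signal value and up to 3 unmarked genes in alphabetical order, the 10 genes with the widest merged domains, the 10 genes with the most distal peaks, and the 5 strongest peaks of each replicate without overlap in the other.

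The alternatives tried were other definitions of overlap, peaks with −log10 q of at least 3, the 20000 strongest peaks, promoter windows of 500 bp and 2.5 kb, the pooled list, each replicate's own list, 1 start site per gene, random lists matched on CpG decile, a domain window of 2.5 kb, a distal distance of 5 kb and random lists not matched on territory. The tests were tested on simulated data with 18 lists among 21853 genes. With 95% or 30% of a list marked against 65% of all genes, 93.2% of raised and 85.3% of lowered lists were called in 100 simulations, and 2.83% of unchanged lists. A 2-fold change of domain width was called in 88.3% of widened and 85.0% of narrowed lists, and in 6.67% of unchanged lists. The simulated width lists kept all their genes, but the real test used marked genes only. These numbered 2 for liver, 3 for germ cells, 4 for erythroid cells and 5 each for Hox and microglia genes, and the simulated rates do not apply to lists that small. A 2-fold change of distal peaks was called in 3.33% of raised lists, a 5-fold change in 73.3% and a 10-fold change in 95.0%. Lowered distal counts were called in 3.33%, 45.8% and 81.7% of lists at those folds. No call had the wrong direction.

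Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, together with bedtools 2.31.1 and samtools 1.23.1. The text files deposited with the samples hold no measurements and were only read for how the lists derive from each other.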

Results

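H3K9ac, a histone acetylation found at active promoters and enhancers, was mapped by ChIP-seq in mouse forebrain at embryonic day 13.5. At this stage the tissue holds dividing radial glia and the newborn neurons they produce. The data came from 1 group of 2 biological replicates, each a pool of male and female embryos. Replicate 1 had 76516 peaks covering 40.8 Mb, and replicate 2 had 69628 peaks covering 38.7 Mb. The pooled list had 98701 peaks over 55.4 Mb. The replicated list had 40878 peaks over 41.4 Mb, 1.57% of the sequenced genome. Median peak width was 267 bp in replicate 1, 276 bp in replicate 2, 286 bp in the pooled list and 679 bp in the replicated list. The read depth behind the peaks is not given in the sources used here. The labels state no question beyond mapping the mark in this tissue, so the comparisons are between the replicates and between gene groups within the replicated list.

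The strongest H3K9ac sites were found in both replicates, and most of the weakest were not. All 34 telencephalic patterning and neurogenic factors, all 24 radial glia genes and all 32 newborn neuron genes had a promoter peak in each replicate, as did all 67 ribosomal protein genes. In replicate 1, 50.9% of peaks (38920 of 76505) overlapped a peak of replicate 2 by at least 1 bp. In replicate 2, 56.2% (39103 of 69616) overlapped a peak of replicate 1, for a mean of 53.5% over both directions. Both shares come from a single comparison of the same lists, so they carry no error between replicates. Random placement gave a mean of 3.23% for replicate 1 (3.10 to 3.42 over 100 placements) and 3.55% for replicate 2 (3.39 to 3.74). In the decile with the highest signal values, 100% of peaks overlapped in either direction. In the lowest decile the shares were 25.5% and 26.9%. Overlapping peaks had a median signal value of 4.36 in replicate 1 and 4.73 in replicate 2, against 2.78 and 2.99 for the others. Among the 20000 strongest peaks of each list, 88.2% overlapped.

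**Figure D1:**
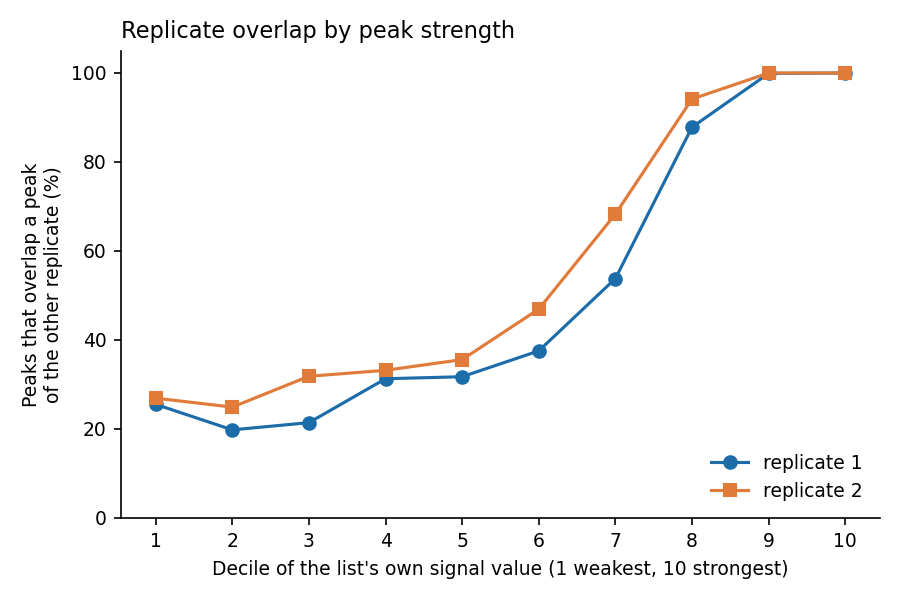
Share of each replicate's peaks (%, vertical axis) that overlap a peak of the other replicate by at least 1 bp, by decile of the list's own signal value (horizontal axis, 1 weakest, 10 strongest). Circles are replicate 1 and squares replicate 2; the share reaches 87.8% and 94.1% in decile 8 and 100% in decile 10.

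The order of strength was largely shared. Across 38920 overlapping peaks, Spearman's rho of the signal values was 0.772 with replicate 1 as reference, and 0.761 across 39103 peaks with replicate 2 as reference. Peaks are not independent replicates, so no p was computed. The strongest peaks without a partner had signal values up to 6.42 in replicate 1 and 6.55 in replicate 2, above the medians of overlapping peaks. In replicate 1 the strongest lay in an intron at 12.3 kb from a start site of Ahdc1 (chromosome 4, 133051753 to 133052223, signal value 6.42). Next came peaks whose nearest start sites were those of Cuedc2 (0.22 kb away), Frrs1 (30.1 kb), Gmnc (0 kb) and Satb1 (276 kb). In replicate 2 the strongest was intergenic, 32.6 kb from Tmem212 (chromosome 3, 27863570 to 27863797, signal value 6.55). The nearest start sites of the others were those of Mast4 (94.1 kb away), Mki67 (330 kb), Nme1 (0.007 kb) and Atp6v1g3 (112 kb). All 10 of these peaks overlapped both the pooled and the replicated list, although each was absent from the list of the other replicate.

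The replicated list held the stronger part of the pooled list. All 40869 of its peaks on chromosomes 1 to 19, X and Y were identical to pooled peaks, and they made up 41.4% of the pooled peaks. In the strongest decile of pooled peaks 100% were kept, in decile 7 53.1%, and in the weakest 3.65%. At least 50% of the length was covered by both replicate lists in 65.1% of replicated peaks (26595). At 1 bp, 81.4% touched both, 17.3% (7087) touched exactly 1 replicate list and 1.22% (497) touched neither. A replicated peak was therefore not always a peak called separately in each replicate. The 33111 pooled peaks that shared 50% of either peak's length with both replicate lists were all kept. A further 7758 were kept without that overlap, with a median signal value of 2.91 against 5.19.

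H3K9ac was concentrated at promoters. Of the replicated peaks, 43.9% (17956; 95% CI 43.5 to 44.4) lay within 1 kb of a protein-coding start site, 11.3 times the 3.90% of random placements. A further 13.0% lay in exons, 27.4% in introns and 15.7% between genes, against 10.9%, 35.9% and 49.3% by random placement. Promoter peaks were stronger and wider than the rest, with a median signal value of 10.8 and a median width of 1291 bp. Intron peaks had medians of 3.17 and 446 bp, and intergenic peaks 3.38 and 480.5 bp. Promoter peaks were 97.5% of the strongest decile and 10.6% of the weakest. There were 19471 distal peaks, with a median distance to a start site of 19.9 kb. Both replicates were touched by 70.8% of distal peaks and by 95.2% of promoter peaks. The promoter share depended on the list: it was 30.7% ± 1.76 (SD, n = 2) in the replicate lists and 22.9% in the pooled list.

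A promoter peak was found at 64.7% of protein-coding genes (14135 of 21853; 95% CI 64.0 to 65.3). The replicate lists gave 65.9% ± 0.0356 (SD, n = 2), and 98.8% of the marked genes were marked in both. Marking followed CpG content, a feature of most housekeeping and developmental promoters. In the decile of lowest CpG ratio 5.22% of genes were marked, in the fifth 80.4%, and in the highest 99.0%. Because of this steep relation, each gene list was also compared with random lists matched on CpG decile.

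**Figure D2:**
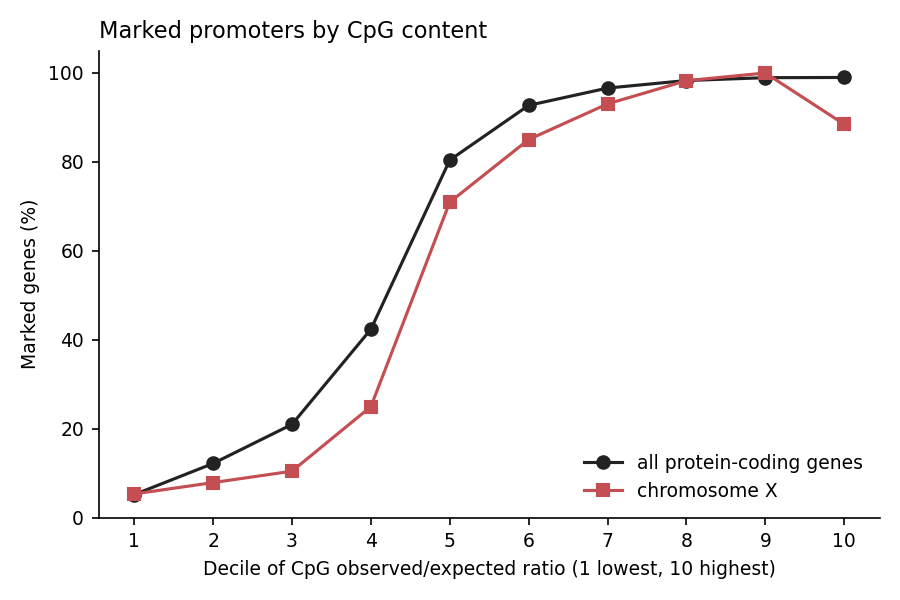
Marked protein-coding genes (%, vertical axis) by decile of the CpG observed over expected ratio at the most upstream start site (horizontal axis, 1 lowest, 10 highest). Circles are all genes and squares genes on chromosome X. The share rises from 5.22% to 99.0% over all genes, and in decile 4 it is 42.4% over all genes and 25% on chromosome X.

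The genes that pattern the forebrain and drive neurogenesis carried H3K9ac without exception among the 3 lists for telencephalon, radial glia and newborn neurons. All 34 telencephalic factors were marked, with the highest signal values at Meis2 (38.3; chromosome 2, 115863064 to 116065839), a homeobox factor of the ventral telencephalon, Foxg1 (36.8; chromosome 12, 49382660 to 49386861), which specifies the telencephalon, Nr2f1 (33.8; chromosome 13, 78188973 to 78199757), a regulator of cortical area identity, and Lhx2 (32.4; chromosome 2, 38339281 to 38369733), a cortical selector gene. All 24 radial glia and progenitor genes were marked, led by Msi1 (43.3), an RNA-binding protein of neural stem cells, Id4 (33.8), an inhibitor of basic helix-loop-helix factors, the Notch target Hes5 (31.2; its peak also lies at Pank4) and Sox1 (30.1), an early neural transcription factor. All 32 newborn neuron genes were marked, led by Sox4 (46.2; chromosome 13, 28948919 to 28953713) and Sox11 (41.2), which promote neuronal differentiation, Pou3f3 (38.6), a factor of upper-layer neurons, and Bcl11b (33.0), which specifies subcerebral projection neurons. The median over all marked genes was 14.4. Foxg1 shared its peak with the start site of the predicted gene Gm43517.

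Against 64.6% of other genes, these 3 lists gave adjusted p of 2.44e-06 for telencephalic factors, 0.00011 for radial glia genes and 5.36e-06 for newborn neuron genes by Fisher's exact test. The 95% intervals began at 89.7%, 85.8% and 89.1%. Lists matched on CpG decile were marked at 91.2%, 87.5% and 78.1%, with adjusted permutation p of 0.0673, 0.0444 and 0.0012. The call for telencephalic factors thus ended, at a difference of 8.82 points.

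Regulators of the diencephalon and hypothalamus, the caudal forebrain, were marked at 18 of 20 genes (90.0%; 95% CI 68.3 to 98.8), with lower signal values. Tcf7l2, a factor of the developing thalamus, had 16.1, Olig2, a factor of ventral progenitors, 11.5, Fezf1 7.93 and Lhx5 7.67. The hypothalamic factors Hmx2 and Otp were unmarked. The adjusted exact p was 0.0267, and the replicates gave 92.5% ± 3.54 (SD, n = 2). The call ended with CpG-matched lists (90.0%, adjusted permutation p = 1) and with 1 start site per gene (adjusted exact p = 0.056).

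Among genes of more posterior neural tissue, most Hox genes had no H3K9ac peak at their promoters, while most midbrain and hindbrain regulators did. Of 39 Hox genes, which pattern the hindbrain and trunk, 5 were marked (12.8%; 95% CI 4.30 to 27.4), against 64.8% of other genes (adjusted p = 2.61e-10, Fisher's exact test) and 87.2% of CpG-matched lists (adjusted permutation p = 0.0012). These were Hoxa7 (4.63), Hoxa1 (4.15), Hoxd8 (3.83), Hoxd1 (3.29) and Hoxd13 (3.26), the last outside the naming rule and chosen after its value was seen. Hoxa10, Hoxa11 and Hoxa13 were among the unmarked. Midbrain and hindbrain regulators were marked at 14 of 20 genes (70.0%; 95% CI 45.7 to 88.1; adjusted exact p = 0.816), but CpG-matched lists reached 90.0%, a difference of −20.0 points (adjusted permutation p = 0.0084). Mafb, which patterns hindbrain segments, had 16.1, En1, a midbrain and hindbrain patterning factor, 6.34, Pou4f1 5.55 and the organizer signal Fgf8 4.62, while Barhl1, the serotonergic factor Fev and Lbx1 were unmarked. The replicates gave 72.5% ± 10.6 (SD, n = 2) for this list and 16.7% ± 1.81 for Hox genes. Against all other genes the midbrain and hindbrain list also turned below within 500 bp (−4.09 points), with 1 start site per gene (−6.91) and without replicate 1 (−0.946).

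Genes of glia and mature neurons, most of which rise later, were marked at 21 of 28 (75%; 95% CI 55.1 to 89.3). The share did not differ from other genes (adjusted exact p = 0.448), but it was 17.9 points above CpG-matched lists (adjusted permutation p = 0.0337). CpG content was taken at the most upstream start site only, so genes marked at another start site can widen this gap. With 1 start site per gene the unmatched difference was 2.39 points. The highest signal values were at Rbfox3 (20.3), a marker of postmitotic neurons, Mbp (16.2), the myelin basic protein gene, at its most upstream start site (peak at chromosome 18, 82474709 to 82476867), the synaptic vesicle gene Syt1 (14.4) and the gap junction gene Gja1 (10.8), which radial glia also express. The myelin genes Mag and Mobp and the astrocyte gene Aldh1l1 were unmarked.

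**Figure D3:**
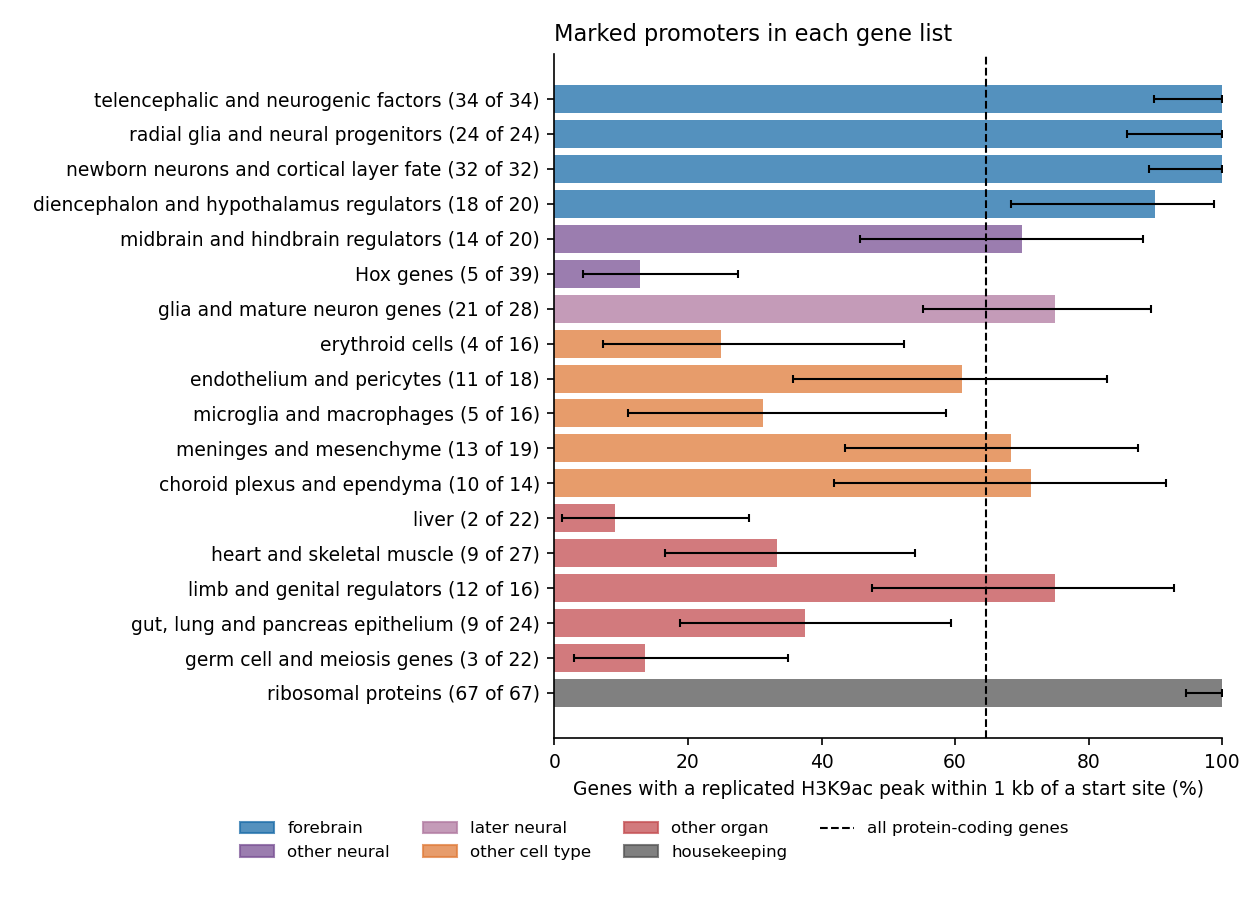
Share of genes with a replicated H3K9ac peak within 1 kb of a start site (%, horizontal axis) in each of the 18 lists, colored by kind of list. Whiskers are exact 95% binomial intervals and the dashed line is the 64.7% of all protein-coding genes; 4 lists lie at 100%, and liver lies lowest at 9.09%.

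Markers of non-neural cells that forebrain tissue also holds gave a mixed picture. Erythroid genes were marked at 4 of 16 (25%; 95% CI 7.27 to 52.4; adjusted exact p = 0.00471), namely the erythroid factor Klf1 (7.42), the glycophorin gene Gypa (7.13), the erythropoietin receptor gene Epor (4.76) and the blood factor Tal1 (3.30), while Alas2, Ermap and Gata1 were not. Microglia and macrophage genes were marked at 5 of 16 (31.2%; 95% CI 11 to 58.7; adjusted exact p = 0.0137), led by Irf8 (7.12), Runx1 (3.70), Aif1 (2.95) and Tmem119 (2.83), while the complement genes C1qa and C1qb and the receptor gene Csf1r were unmarked. CpG-matched lists were marked at 25% and 31.2%, so both calls ended (adjusted permutation p = 1 for each). The microglia call also ended in the pooled list (adjusted exact p = 0.228) and without replicate 1 (0.103) or without replicate 2 (0.104).

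The other 3 lists of non-neural cells did not differ from other genes, each with an adjusted exact p of 0.816. Endothelium and pericyte genes were marked at 11 of 18 (61.1%; 95% CI 35.7 to 82.7), led by the vascular growth factor receptor gene Kdr (9.21), Erg (5.94), the tight junction gene Cldn5 (5.42) and the pericyte gene Kcnj8 (5.02), with Cdh5, Emcn and Pecam1 unmarked. Meninges and mesenchyme genes were marked at 13 of 19 (68.4%; 95% CI 43.4 to 87.4), led by Zic1 (22.5), which neural progenitors also express and whose peak also lies at Zic4, Prrx1 (13.5), Zic3 (10.7) and Foxd1 (7.0), with Col3a1, Dcn and Lum, genes of extracellular matrix, unmarked. Choroid plexus and ependyma genes were marked at 10 of 14 (71.4%; 95% CI 41.9 to 91.6), led by the ciliogenesis factor Foxj1 (9.91), Rspo3 (9.25), Otx2 (8.33) and the roof plate factor Lmx1a (6.47), with Aqp1, Cldn2 and Folr1 unmarked. Without replicate 2 the small differences turned to 0.772 points for endothelium and −2.74 points for meninges.

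Genes of other organs were mostly without the mark. Liver genes were marked at 2 of 22 (9.09%; 95% CI 1.12 to 29.2; adjusted exact p = 5.49e-07), and germ cell genes at 3 of 22 (13.6%; 95% CI 2.91 to 34.9; adjusted exact p = 4.16e-06). Gut, lung and pancreas genes were marked at 9 of 24 (37.5%; 95% CI 18.8 to 59.4; adjusted exact p = 0.0144), and heart and skeletal muscle genes at 9 of 27 (33.3%; 95% CI 16.5 to 54.0; adjusted exact p = 0.00229). The 2 marked liver genes were Foxa3 (20.1) and Apoh (17.4), and both peaks also lay at a start site of another gene, Sympk and Prkca respectively. The serum protein genes Alb, Afp and Ahsg were unmarked. In muscle the fast myosin light chain gene Mylpf had 26.9, at a peak shared with Tbc1d10b, followed by Ryr1 (4.74), Gata6 (4.49) and Nppa (3.66), while the sarcomere genes Acta1 and Actc1 and the creatine kinase gene Ckm were unmarked. The epithelial genes Epcam (5.68), Krt18 (5.02) and Cdh1 (4.52) were marked, and the endoderm factors Cdx1, Cdx2 and Foxa2 were not. The meiotic genes Prdm9 (12.4) and Dmc1 (4.35) and the germ cell gene Dazl (6.87) were marked, and Acrv1, Bmp15 and Ddx4 were not.

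CpG-matched lists were marked at 31.8% for liver (adjusted permutation p = 0.0283), 63.6% for germ cells (0.0012), 62.5% for gut, lung and pancreas (0.00216) and 48.1% for heart and muscle (0.0929), so the last call ended. In the pooled list the calls for heart and muscle (adjusted exact p = 0.0674) and for gut, lung and pancreas (0.117) ended. Limb and genital regulators were the exception among other organs, with 12 of 16 marked (75%; 95% CI 47.6 to 92.7; adjusted exact p = 0.574). They were led by Satb1 (18.3), a chromatin organizer that cortical interneurons also express, the collagen gene Col2a1 (11.6), the bone factor Runx2 (9.38) and the cartilage gene Acan (6.47), with Alx1, Nkx3-2 and Pitx1 unmarked.

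Ribosomal protein genes, active in all cells, were marked at 67 of 67 (95% CI 94.6 to 100; adjusted exact p = 4.23e-12), against 92.5% of CpG-matched lists (adjusted permutation p = 0.0018). The highest signal values were at Rpl9 (34.6; its peak also lies at Lias), Rps6 (33.7), Rps19 (33.1) and Rps8 (31.96), and the median of the list was 24.5. The median signal values of marked genes were 17.7 for telencephalic factors, 20.1 for radial glia and 15.1 for newborn neurons. They were 18.8 for the 2 liver genes, whose peaks are shared with other genes, 7.18 for glia and mature neurons, 6.87 for germ cells, 6.03 for meninges, 5.94 for erythroid cells, 5.75 for diencephalic regulators and 5.73 for choroid plexus. The lowest were 4.93 for limb regulators, 4.74 for endothelium, 4.49 for gut, lung and pancreas, 3.83 for Hox genes, 3.57 for heart and muscle, 3.50 for midbrain and hindbrain regulators and 2.95 for microglia genes. In total 5 lists were marked more often than other genes and 7 less often by Fisher's exact test, over 18 lists, and in the pooled list 4 were marked less often. Genes are not replicates, so these tests describe this peak list and not variation between embryos.

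The telencephalic, radial glia and newborn neuron lists, but not the diencephalic list, also had wider H3K9ac than random lists. Marked telencephalic factors had a median of 7671 bp under peaks within 5 kb of their start sites, newborn neuron genes 6175 bp and radial glia genes 5500 bp, against 2147 bp over all marked genes. The replicates gave 6746 ± 144, 5759 ± 317 and 4968 ± 275 bp for these lists (SD, n = 2). Among single genes, Lhx2 had 20722 bp (replicates 19739 ± 74.95, SD, n = 2), Nr2f1 12975 bp (12708 ± 223) and Msi1 12659 bp (12094 ± 29.7). This measure can grow with the number and spread of a gene's start sites, on which the random lists were not matched. Ribosomal protein genes, although stronger in signal, had a median of 2962 bp. Narrower than random lists were Hox genes (500 bp), heart and muscle (604), germ cells (711), gut, lung and pancreas (749), microglia (813), midbrain and hindbrain regulators (934.5), endothelium (1175) and limb regulators (1252).

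By 10000 random lists of marked genes, the adjusted permutation p was 0.00072 for each of the 3 wide forebrain lists, whose raw p was the smallest the random lists can give, and 0.00103 for ribosomal proteins. For the 8 narrower lists it lay between 0.00072 and 0.0237. Diencephalic regulators (2823 bp), glia and mature neurons (2159), meninges (1598), choroid plexus (1544), erythroid cells (1169.5) and liver (2394) did not pass. With 4 marked erythroid genes and 2 marked liver genes, a failure to pass says little for those lists. Liver turned narrower by the pooled list (−2014 bp from random lists), and by either replicate list, as did glia without replicate 2 (−77.0 bp) and diencephalic regulators with a 2.5 kb window (−38.0 bp). The liver difference in the pooled list passed (adjusted permutation p = 0.00045), as did a wider diencephalic list there (0.0337), a narrower meninges list without replicate 1 (0.0188) and a narrower choroid plexus list without replicate 2 (0.0324). Matching on CpG decile ended the calls for endothelium (adjusted permutation p = 0.105), microglia (0.119) and limb (0.0598). The pooled list ended those for midbrain and hindbrain (adjusted permutation p = 0.0579), limb (0.0822) and germ cells (0.092), and the last also ended without replicate 2 (0.293).

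Merged domains, a measure other than the width within 5 kb of start sites, gave another order. Among protein-coding genes, Nr2f1 had the widest merged domain, at 41.7 kb (chromosome 13, 78170210 to 78211887; replicates 38.2 ± 3.97 kb, SD, n = 2). Next came Pou3f3 at 31.7 kb (chromosome 1, 42683345 to 42715034; 33.7 ± 3.04), Foxg1 with Gm43517 at 30.4 kb (chromosome 12, 49372898 to 49403332; 29.7 ± 0.610) and Nr2f2, a relative of Nr2f1 in the caudal ganglionic eminence, at 29.7 kb (chromosome 7, 70342849 to 70372586; 29.8 ± 1.03). The interneuron factors Dlx5 and Dlx6 shared a domain of 29.6 kb (chromosome 6, 6853337 to 6882932; 31.1 ± 1.75). Bcl11a, a factor of cortical projection neurons, had 27.9 kb together with A830031A19Rik (chromosome 11, 24073361 to 24101260; 27.6 ± 0.301), and Nfix, a factor of radial glia, had 27.5 kb (chromosome 8, 84763683 to 84791163; 27.4 ± 1.97). The median of all 29838 merged domains was 1.01 kb.

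Distal H3K9ac peaks were more frequent around the same 3 lists, and the diencephalic list did not pass. Newborn neuron genes had 8.22 distal peaks per gene (263 peaks), radial glia genes 8.12 (195) and telencephalic factors 7.12 (242), against medians of 1.66, 1.5 and 1.53 in random lists matched on territory. Of the genes named in these lists, Sox4 had 31, Bcl11b 30, Pou3f3 20, Nr2f1 19, Sox11 19, Id4 19, Meis2 18, Sox1 13, Msi1 10, Lhx2 7, Hes5 5 and Foxg1 1. The low count of Foxg1 depends on the nearest start site, as Gm43517, which shares its promoter peak, was given 11. The replicate lists, which hold more weak peaks, gave 13.9 ± 0, 12.4 ± 0.501 and 12.1 ± 0.707 per gene (SD, n = 2). The adjusted permutation p was 0.0012 for each of these lists, from the smallest raw p the random lists can give. The random lists were not matched on the GC content of the territories, so its share in the excess is unknown. Peaks of a wide merged domain that lay over 2.5 kb from every start site also counted as distal. Domain width and distal counts are therefore not separate results, and the part of the excess that lay in such domains was not counted.

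No other list passed this test, in either direction. Diencephalic regulators had 4.35 distal peaks per gene and ribosomal proteins 1.28 (adjusted permutation p = 0.0878 for both), limb regulators 2.75, midbrain and hindbrain regulators 2.25, glia and mature neurons 2.11, choroid plexus 1.5, microglia 1.31, meninges 0.947, heart and muscle 0.926, gut, lung and pancreas 0.583, endothelium 0.50, erythroid cells 0.250, liver 0.182, germ cells 0.136 and Hox genes 0.0769. At an unadjusted permutation p under 0.05, 3 lists had fewer: Hox genes (0.0404), liver (0.0478) and germ cells (0.037). By the same measure diencephalic regulators (0.0214) and ribosomal proteins (0.0244) had more. Hox genes passed in the pooled list (adjusted permutation p = 0.0108), without replicate 1 (0.042), without replicate 2 (0.0009) and without matching on territory (0.0027). Germ cell genes passed without replicate 1 (0.042) and without matching on territory (0.0492). Ribosomal proteins had more in the pooled list (0.0259) and without replicate 1 (0.042), as did diencephalic regulators without matching on territory (0.0115). Without that matching the difference for meninges turned to 0.158 peaks per gene. In simulated lists a 5-fold decrease was called in 45.8% of cases, so a loss of that size could often be missed.

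**Figure D4:**
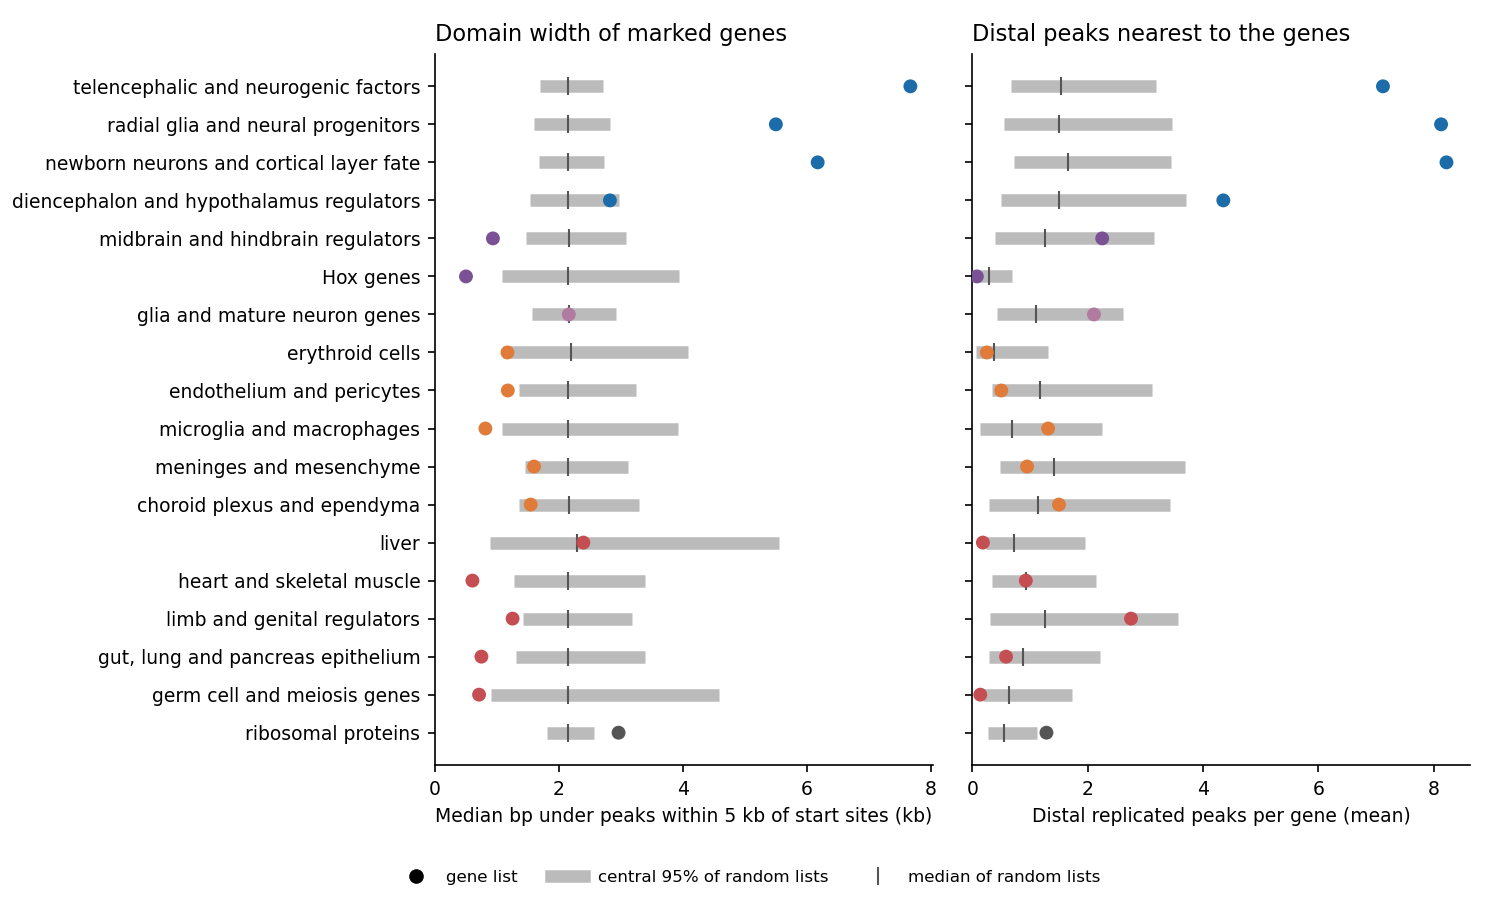
For each of the 18 lists, the median bp under peaks within 5 kb of the start sites of marked genes (left, kb, horizontal axis) and the mean number of distal replicated peaks per gene (right, horizontal axis). Dots are the lists, gray bars the central 95% of random lists and ticks their median. The telencephalic, radial glia, newborn neuron and ribosomal protein lists lie above the bars in both panels, and Hox and germ cell genes lie below them in both. The distal counts of the ribosomal protein, Hox and germ cell lists did not pass after adjustment.

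The genes with the most distal peaks were Gse1 with 100 (chromosome 8, 120228456 to 120581390; replicates 168 ± 5.66, SD, n = 2), Zmiz1 with 55 (89.5 ± 4.95), a transcriptional coactivator, and the predicted gene Gm26897 with 54 (84.5 ± 2.12), which had no promoter peak. They were followed by Prdm16 with 49 (76.0 ± 0), a regulator of neural stem cells, the corepressor gene Ncor2 with 43 (66.5 ± 6.36), Zfp608 with 43 (65 ± 7.07), the RNA-binding protein gene Msi2 with 39 (60.0 ± 7.07), Zfhx3 with 38 (72.5 ± 4.95), Auts2 with 37 (68.0 ± 0) and Zfp423 with 33 (59.0 ± 4.24). Of the 491 distal peaks of these 10 genes, 73.5% lay within the gene itself, against 46.3% of other distal peaks. Their median signal value was 3.30, against 3.30 for other distal peaks.

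Genes on chromosome X were marked less often than autosomal genes. On X 454 of 948 genes were marked (47.9%; 95% CI 44.7 to 51.1), against 13678 of 20722 on autosomes (66.0%), an odds ratio of 0.473 (p = 7.99e-29, Fisher's exact test). The replicates gave 48.4% ± 0.0746 on X and 67.3% ± 0.0375 on autosomes (SD, n = 2). Of the X genes picked by the naming rule, Zic3 was marked, while the erythroid genes Alas2 and Gata1, the tight junction gene Cldn2 and the oocyte gene Bmp15 were not. The rule picked them by list, so they do not represent X genes as a whole. Autosomal lists matched on CpG decile were marked at 56.6% (central 95% 54.6 to 58.9; permutation p = 0.0002, the smallest the random lists can give), which brings the difference from −18.1 to −8.76 points. Among genes without shared promoter sequence and with CpG matching it was −3.0 points (63.9% against 66.9%, permutation p = 0.02), a comparison chosen after the result was seen. Marked X genes had a median signal value of 8.32 and a median width of 1539 bp, against 14.6 and 2172 bp on autosomes.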

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

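The tests of CpG content and shared sequence together on chromosome X, and of distal peaks in genes picked on the other replicate, were chosen only after the result was seen, as was the matched signal ratio of X; the other tests in this part were set beforehand. The replicated list had 9 peaks on unlocalized and unplaced contigs, a signal in data that no comparison used. They lay on GL456233 (4 peaks, near Vamp7 with a signal value of 6.74 and near Tmlhe with 4.62), GL456216 (2 peaks, up to 11.5), JH584304 (2 peaks) and GL456370 (1 peak). All samples belong to 1 group, so no biological explanation was tested for the distal peaks or the Hox genes; a single hypothesis on the signal of X is tested among the other observations.

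The 10 genes with the most distal peaks, from Gse1 to Zfp423, were picked for their counts, so an excess in the same counts is fixed by the choice. The 10 genes picked on 1 replicate had, in the other, a median of 12.7 and 9.09 times the number expected from territory length, and 2.94 and 2.30 times that expected from length and GC content (lowest gene 2.04), with 8 and 9 of the original 10 among them. GC content may thus account for much of the excess, but not for all that recurred in the second list. Weak peaks seen in a single replicate were not more frequent there: 72.9% of these distal peaks touched both replicate lists against 70.8% of other distal peaks, a difference of 2.15 points. Uneven mappability or control coverage over these genes was not tested and stays open.

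Fewer marked promoters on chromosome X than on autosomes held after matching on CpG decile (−8.76 points) and among genes whose promoters share no 50-mer with another gene (−9.55 points; 63.9% of 634 X genes against 73.4%). Neither alone accounts for the difference of −18.1 points. With both together, the difference was −3.0 points (63.9% against 66.9%, central 95% 64.4 to 69.2, permutation p = 0.02). This comparison left out the 33.1% of X genes and 17.7% of autosomal genes with shared 50-mers, which may be unmarked for other reasons. It therefore cannot show how much of the deficit came from sequence sharing. A small remainder stays open. It lies close to the edge of the range, and the lower signal of marked X promoters (0.673 times that of autosomes, matched on CpG decile over deciles 5 and above) stays open as a source of it.

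Few marked Hox promoters cannot be put down to CpG content, since the share differed from CpG-matched lists by −74.4 points. Shared sequence was found at 0% of the 34 unmarked Hox genes by the measure of over 50% of 50-mers shared, and the highest share was 2.52%. The rule that keeps replicated peaks removed few, as 14.7% (5 of 34) had a peak in the pooled list. Silencing of Hox genes in forebrain cells may explain the pattern, as a hypothesis that these samples of a single tissue did not test.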

How the results depend on the processing

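All alternatives were set before the results were seen; where a value moved, the cause was not tested unless the alternative's own construction shows it. No paired analysis was possible because all samples belong to 1 group. Of 71 alternatives to the main values, 41 kept them within the replicate spread, the same call or 1.5 times the count, and 30 moved them; none changed direction. Of 360 alternatives for single lists, 317 stayed on their side of the threshold without turning to the opposite sign (some at a difference of 0), 18 lost the call, 13 gained it and 12 reversed. The read depth is unknown, which limits what can be said of weak peaks.

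Replicate overlap of replicate 1 and 2 was 43.5% and 48.7% with at least 50% of the peak covered, 34.8% and 38.2% with reciprocal overlap, 73.2% and 69.4% with −log10 q of at least 3, and 88.2% and 88.2% for the 20000 strongest peaks. Spearman's rho was 0.796 by −log10 p and 0.811 with −log10 q of at least 3. At 1 bp, 81.4% of replicated peaks touched both replicates. The share of peaks at promoters was 41.0% within 500 bp, 52.4% within 2.5 kb, 22.9% in the pooled list, 46.6% with −log10 q of at least 3, and 29.5 to 31.96% when leaving out each replicate in turn. Marked genes were 64.1%, 65.9%, 67.9%, 64.4% and 65.89 to 65.95% in that order of settings, and 61.9% with 1 start site per gene. In the pooled list 4 gene lists were marked less often and 1 had fewer distal peaks; leaving out a replicate gave 1 to 2 with fewer distal peaks, and not matching on territory gave 2. With CpG matching 5 lists were narrower.

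Reversed differences for midbrain and hindbrain promoters were −4.09 points within 500 bp, −6.91 with 1 start site, −20.0 with CpG matching and −0.946 to 14.1 when leaving out each replicate. Leaving out each replicate gave −4.84 to 0.772 points for endothelium and −2.74 to 7.75 for meninges. For domain width the differences were −2014 bp for liver in the pooled list and −755 to −217 bp for liver, −77.0 to 41.0 bp for glia when leaving out each replicate, and −38.0 bp for diencephalic regulators with the 2.5 kb window. Distal peaks of meninges were 0.158 per gene above random lists not matched on territory. Of these, the CpG-matched midbrain and hindbrain list and the pooled liver width passed the threshold.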

Other observations

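The comparisons of gene families, miR-9 genes and signal values on chromosome X were chosen only after other results had been seen. Gene families were formed by symbol stem with at least 20 members, and 110 were compared with CpG-matched random lists, adjusted over the families. Families with more marked genes than matched lists were the zinc finger genes Zfp (339 of 394, 86.0% against 77.9%) and Zbtb (41 of 41 against 90.2%), the axon guidance semaphorins Sema (20 of 20 against 80%), the Rho exchange factors Arhgef (25 of 26 against 73.1%) and the transmembrane genes Tmem (198 of 242, 81.8% against 75.2%). Their adjusted p lay between 0.0027 and 0.0487. The lower families included the olfactory receptors Olfr (2 of 1134 against 10.4%), the vomeronasal receptors Vmn (1 of 331 against 9.37%), the keratins Krt (5 of 53 against 43.4%), the keratin-associated proteins Krtap (1 of 57 against 17.5%) and the defensins Defb (0 of 42 against 14.3%). The others were the clustered protocadherins Pcdhb (0 of 22 against 54.5%), the Rhox homeobox genes (0 of 34 against 44.1%), Tex (12 of 38 against 47.4%) and the histone genes Hist (58 of 67, 86.6% against 97%). The Hist direction turned between the tests, since it lay above all other genes by Fisher's exact test (adjusted p = 0.000197). Shared 50-mers, which limit how well reads can be placed, were present at 88.1% of Hist, 79.4% of Rhox, 70.2% of Krtap, 67.4% of Vmn, 40.5% of Defb, 34.0% of Krt, 28.4% of Olfr, 27.3% of Pcdhb and 23.7% of Tex genes, and at 26.4% of Zfp genes among the higher families. Without CpG matching, Fisher's exact test called 53 families higher and 32 lower.

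The 3 genes of the neural microRNA miR-9, which promotes neurogenesis, lay in 3 of the widest merged domains of the genome, and none of the domains reached a protein-coding start site. Mir9-3 lay in the widest, of 44.3 kb (chromosome 7, 79495738 to 79540081; replicates 38.9 ± 7.69 kb, SD, n = 2), 29.4 kb from Polg. Mir9-1 lay in the domain of rank 3, of 37.3 kb (chromosome 3, 88197061 to 88234363; 41.4 ± 6.95), 20.3 kb from Rhbg. Mir9-2 lay in that of rank 6, of 30.2 kb (chromosome 13, 83712731 to 83742904; 30.04 ± 0.172), 59.8 kb from Mef2c. Because the pattern was noticed from these ranks, it was set against all 9 microRNA families present in at least 2 of the 236 domains that hold a microRNA gene. In 10000 permuted orders of those domains no family ranked as high, a permutation p of 0.0001, the smallest they can give. The choice of microRNA genes as a class followed from the data too, so it remains a hypothesis that miR-9 genes may carry unusually wide H3K9ac in this tissue.

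The lower signal of marked X promoters may reflect fewer active copies of X than of an autosome, since male cells carry a single X and female cells silence the other. Matched on CpG decile over deciles 5 and above, the ratio of median signal values of X to autosomes was 0.673, while each of the 19 autosomes lay between 0.936 and 1.05 of the others. The bounds of this test were written after the unmatched medians had been seen. The ratio was not matched on shared promoter sequence, present at 33.1% of X genes and 17.7% of autosomal genes, so a part played by it stays open. The control also holds fewer copies of X in male cells, so the ratio is not a measure of copy number, and lower activity of X genes for other reasons would give the same result. On chromosome Y, 3 of 183 genes were marked, Uty (4.76), Ddx3y (4.62) and Kdm5d (3.30), in pools that held male embryos. Shared promoter sequence was not compared for Y, so the low count does not show absence of the mark at the other genes.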
